A study of Mus musculus with 16 samples.

How the data were processed

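Whole-brain RNA of 16 male mice was hybridised to Agilent whole-genome mouse arrays in 1 colour. Per the labels' protocols, RNA was isolated from freshly removed brain with an RNeasy kit and labelled with Cy3 by a Low RNA Input QuickAmp kit. Genotype, age and replicate number were taken from the sample labels, in which the values under the strain and age tags are interchanged. The 4 groups were wild type and Slc5a8-deficient at 4 and 18 months, with 4 arrays each. Per the file headers, the spot intensities were read by Agilent Feature Extraction 10.7.3.1, which subtracted background and corrected spatial trends to give the processed intensity, and no scaling between arrays was applied to it. The deposited value table of the whole series holds log2 values. The submitters' processing notes name limma without a version or steps. Its columns ranked the probes as the log2 of the raw median spot intensity did (Spearman's rho of 0.99997 or more on each array), and its medians lay between 6.606 and 6.622, so it was read as quantile-normalized log2 signal without background subtraction, a scale inferred from the values and not stated. It served only as an alternative. Coordinates are those in the scanner files (NCBI37/mm9). No genome sequence was used here.

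Of the intensities, 59305 non-control spots per array were used, for 55681 distinct probes and 34821 gene names. Between 98 and 182 spots per array were flagged as outliers and left out, and 0 were saturated. Spots of the same probe were averaged. The normalized level was log2 of the processed signal minus the array's 75th percentile of it. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which left 33071 probes, 29444 of them well above background on all 16 arrays. Each gene was represented by its kept probe with the highest mean over all arrays, giving 23030 genes, of which 6806 had several kept probes. In the averaged genotype contrast 93 genes had at least 2 called probes and 10 of them had calls in opposite directions, while the other 6 contrasts had 0 or 1 such gene each. Of 29150 probes with a RefSeq-type accession, 27509 matched the GRCm38 gene table, which was used for names only, and 2421 symbols were updated. Names that are only clone or model numbers (8170 genes) were counted but not named in the text, apart from 1 gene model in the closing section that was chosen after its values were seen.

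A means model of the 4 groups was fitted with limma 3.58.1 (under R 4.3.3, with the data.table package at version 1.17.8) to all 16 arrays, which then share 1 estimate of the spread with 12 residual and 2.84 prior degrees of freedom. The 7 contrasts were the genotype difference at each age, the age difference in each genotype, their interaction and the averages over age and over genotype. P-values were moderated by eBayes and adjusted by Benjamini and Hochberg over all genes of a contrast, with a threshold of 0.05. The median difference of all genes stayed within 0.022 of 0 in each contrast. Where a probe was not well above background on any array of a group, the fold was given as a lower bound, the bright group's mean against the mean over the dim group of the higher of the probe's own level and the lowest level among probes well above background on that array. No fold was given for such genes in averaged or interaction contrasts. The design text calls the arrays of a group biological replicates and says no more of the animals. P-values measure the spread between these samples.

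The rule for naming genes, the gene lists, the design and the alternatives were fixed before the data were examined. In each contrast the text names Slc5a8, up to 12 rises and 12 falls with the largest differences among called genes whose 4 arrays of one group all lay above the 4 of the other (the last condition not applied to averaged and interaction contrasts), and, of each list described, members among the 4 with the smallest p. Members counted as called beyond those 4 are named too. A few genes that this rule takes in are not reported here. The rule was met by 222, 196, 60, 370, 20, 269 and 447 genes in the young and old genotype, wild-type and deficient age, interaction, mean age and mean genotype contrasts. Sets of marker genes of tissues bordering the brain were written after the named genes had been seen. The 46 lists held 1152 names, of which 1072 were measured, and were tested with camera at a preset correlation of 0.01 between genes over the 23012 genes without missing values, with camera at a correlation estimated per list, and with fry, whose directional p asks whether a list's genes move on balance one way and compares them with no other genes. A list called with the preset correlation but not with the estimated one is given with both p-values.

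Single values were compared by exact two-sided permutation tests and counts within windows by Fisher's exact test. Alternatives were normexp background correction (offset 50), quantile normalization, centring on the median of probes above background on all arrays, the deposited value table, no filter and a stricter filter on dim probes, all probes or the mean of probes, array weights, an intensity trend with a robust prior, only the 8 arrays compared, the replicate number as a block, and each array left out. Leaving out the 3 arrays that stood apart on the first principal component was added after seeing the data. The scanner files put all 8 deficient arrays on 1 slide and all 8 wild-type arrays on another, each read in its own scan session. Slide and genotype therefore cannot be told apart, and no slide block could be fitted to genotype contrasts. Each age contrast within a genotype lies within 1 slide but goes with its rows, since old deficient and young wild-type arrays lay in row 2 and young deficient and old wild-type arrays in row 1. Age and row therefore cannot be told apart within a genotype, nor row and interaction, whereas an additive row difference cancels in both averaged contrasts. Arrays of a group correlated with r of 0.975 to 0.995, and no 2 arrays of a group held identical values (SD of their difference at least 0.323).

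The fit was tested on simulated data with 200 of 23012 genes changed by 1.5-fold (67 genes), 2-fold (67) or 4-fold (66). It recovered 28.4%, 70.1% and 97.0% of them for the young genotype difference, 32.8%, 67.2% and 93.9% for the age difference in wild type and 13.4%, 59.7% and 77.3% for the interaction, with 16, 6 and 4 unchanged genes called. A list of 25 genes shifted by 0.3 was called in each of the 7 contrasts, and 0 of 45 lists left unshifted were called. The simulated genes varied independently of each other. The check therefore does not show how often camera with the preset correlation calls lists whose genes vary together. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.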

Results

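Gene expression was measured in whole brains of male mice with and without the transporter Slc5a8, on 16 Agilent whole-genome arrays read in 1 colour (Cy3). Slc5a8 is a sodium-coupled transporter of monocarboxylates such as lactate, pyruvate and ketone bodies. Wild-type and Slc5a8-deficient mice, given as C57BL/6J in the labels, were compared at 4 months (young) and 18 months (old), with 4 arrays in each of the 4 groups, which the design text calls biological replicates. Each array carried 59305 non-control spots, of which 58.4% to 66.1% were well above background, and the 75th percentile of the processed signal ran from 626 to 1348. After the filter on dim probes, 23030 genes were tested. All differences below are log2 differences ± SE from limma's 4-group fit with n = 4 arrays per group, a gene is said to have risen, fallen or been called when its Benjamini-Hochberg adjusted p was under 0.05, and levels are log2 signals relative to the array's 75th percentile. The number of arrays limits the precision of every value. The first principal component held 29.5% of the variance, and array 1 of the young deficient group lay at 97.2 on it, with array 2 of the old wild type at 26.5 and array 4 of the young wild type at 26.1.

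**Figure D1:**
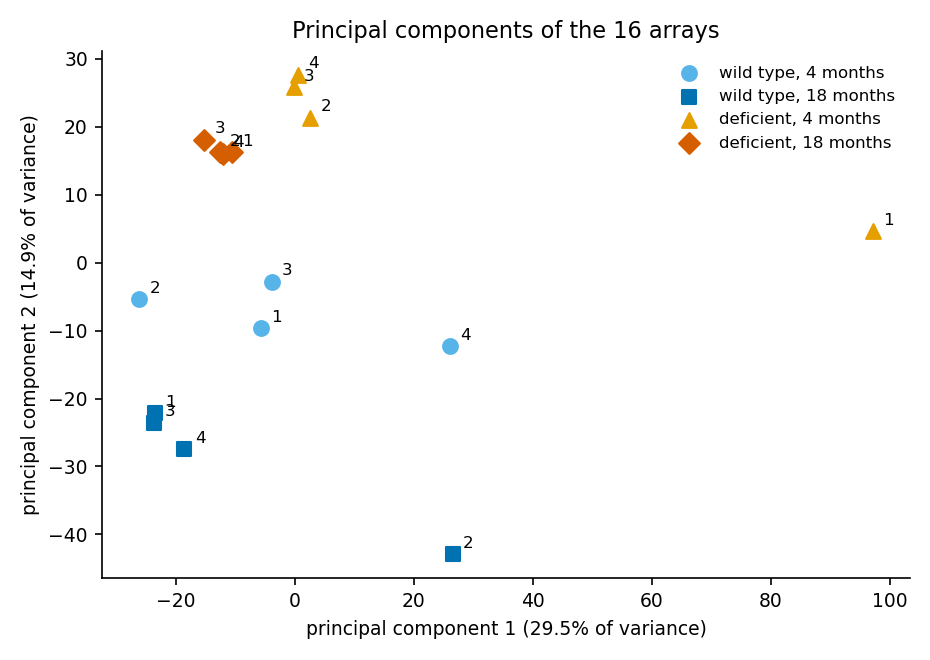
Positions of the 16 arrays on the first 2 principal components of the normalized log2 signals (arbitrary units), 1 point per array with its replicate number, coloured by group. Array 1 of the young deficient mice lies at 97.2 on the first component, far from the other 15.

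The targeted gene was examined first. Its probe lies at position 4958 of the transcript, on chromosome 10 from 88391888 to 88391947 (NCBI37/mm9), and was printed as 10 spots per array. It was not well above background on any of the 16 arrays. Its mean level was -7.22 ± 0.62 (SD, n = 4) in young deficient and -7.27 ± 0.38 in young wild-type brains, a difference of 0.05 (exact two-sided permutation p = 0.886). In old mice the levels were -7.49 ± 0.55 and -7.05 ± 0.16, a difference of -0.45 (exact permutation p = 0.2, where 0.0286 is the smallest possible value). The deleted part of the gene is not given in the labels, and a probe outside it, or one whose transcript is too scarce to read in whole brain, checks nothing about the genotype labels.

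The comparison of deficient with wild-type brains at 4 months asked which transcripts differed in the absence of the transporter in young adults. In the young deficient mice 155 genes were higher and 198 lower, and 237 of the 353 differed by more than 1.5-fold. The kallikreins Klk1b22 (4.54 ± 0.93, adjusted p = 0.028) and Klk1b3 (2.87 ± 0.58, adjusted p = 0.026) on chromosome 7 were among the largest rises. Zfp963, a zinc finger gene on chromosome 8 (72265659 to 72265718), was higher by 3.12 ± 0.25 (adjusted p = 1.2e-05) and Ocel1, on the same chromosome, by 2.76 ± 0.28 (adjusted p = 0.00011). Also higher were the fucosyltransferase Fut1 (2.53 ± 0.42, adjusted p = 0.0081), Ccr6, the receptor of the chemokine Ccl20 (2.51 ± 0.38, adjusted p = 0.0043), the photopigment melanopsin Opn4 (2.23 ± 0.25, adjusted p = 0.00035), Wdfy1 (2.19 ± 0.18, adjusted p = 1.6e-05) and netrin Ntn4 (2.08 ± 0.13, adjusted p = 1.4e-06). Ttll2 was not well above background on any young wild-type array and was at least 2.78-fold higher in the deficient mice (adjusted p = 0.0017). Pla2g4e (2.43 ± 0.45) and Comp (2.16 ± 0.34) completed the 12 largest rises.

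Of the 12 largest falls in the young deficient mice, 7 were on chromosome 9. Of these, Ppcdc, an enzyme of coenzyme A synthesis, and the growth factor Nrg4 were not well above background on any young deficient array, and were at least 3.91-fold (adjusted p = 0.0029) and at least 2.24-fold lower (adjusted p = 0.033). Tmem25 (-2.39 ± 0.32, adjusted p = 0.0014), the carotenoid-cleaving oxygenase Bco2 (-2.13 ± 0.29, adjusted p = 0.0017), the protease Tmprss4 (-1.97 ± 0.36, adjusted p = 0.015), Bfsp2 (-2.16 ± 0.49, adjusted p = 0.043) and Ccdc153 (-1.70 ± 0.31, adjusted p = 0.014) were lower as well. Genes elsewhere included the chemokine Ccl28 (-2.51 ± 0.48, adjusted p = 0.018), Plac9a (-2.12 ± 0.31), Dctd (-2.10 ± 0.47), Sult1c2 (-1.95 ± 0.40) and S100a5, a calcium-binding protein of olfactory neurons (-2.05 ± 0.41, adjusted p = 0.025). In the dimmer group, Opn4, Ccl28, Sult1c2 and Tmprss4 were well above background on 1 of 4 arrays, Klk1b22 and Fut1 on 2, and Klk1b3 and Dctd on 3. Of the 24 genes named by rule, 11 were called under every alternative that tested them and without each array in turn, namely Zfp963, Ocel1, Fut1, Ccr6, Opn4, Wdfy1, Ntn4, Ppcdc, Tmem25, Bco2 and Plac9a. With normexp Klk1b22, Klk1b3, Ttll2, Nrg4, Ccl28, Dctd, Tmprss4 and Sult1c2 were no longer called and differed by amounts more than 1.5 times smaller (adjusted p up to 0.249, for Sult1c2), and so did Nrg4 and Sult1c2 in the deposited table. Another probe of Dctd, above background on all 16 arrays, gave -0.13 (adjusted p = 0.699). All deficient arrays shared 1 slide and scan session and all wild-type arrays another, so slide and genotype cannot be told apart in this and every other genotype comparison. At each single age the genotypes also lay in different slide rows.

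Of 46 gene lists fixed beforehand, 10 passed camera with a preset correlation between genes in the young comparison, 8 of them lower in the deficient mice. With an estimated correlation none passed (4 at an unadjusted p under 0.05), and fry passed 5. Interferon-stimulated genes were lower for 26 of 34 members (median -0.24, adjusted p = 4.9e-05; adjusted p = 0.48 with an estimated correlation). Of these, 3 were called over all genes and 6 when adjusted over the list alone. The called members were the antiviral enzyme Oas2 (-0.86 ± 0.17), Ifi27l2a (-0.75 ± 0.17) and Irgm1 (-0.48 ± 0.10). Heat shock proteins and chaperones were lower for 21 of 25 (median -0.14, adjusted p = 8.4e-05; adjusted p = 0.48 with an estimated correlation), with medians of -0.22 without array 2 of the young deficient and -0.23 without array 4 of the young wild type. Cryab (-1.15 ± 0.17) and Dnaja1 (-0.39 ± 0.09), 2 members, were called over all genes and 6 adjusted over the list alone. Of the unfolded protein response, 19 of 28 members were lower (median -0.19, adjusted p = 0.00073; adjusted p = 0.48 with an estimated correlation). Manf was called (-0.72 ± 0.16). Ependymal and ciliary genes were lower for 20 of 23 (median -0.32, adjusted p = 7e-05; adjusted p = 0.57 with an estimated correlation), with Ccdc153 called. Choroid plexus markers were lower for 25 of 26 (median -0.71, adjusted p = 2.7e-06; adjusted p = 0.63 with an estimated correlation). No single choroid plexus marker was called by limma, 8 had an unadjusted p under 0.05, and the list's fry adjusted p was 0.257. On array 1 of the young wild-type mice this list stood 1.58 above its mean over all arrays, and without that array its median was -0.37 and that of the ependymal list -0.19, both still called. The pituitary and pineal list, which stood at 2.37 on the same array, did not pass (9 of 10 lower, median -0.88, adjusted p = 0.144). Marker sets of tissues at the edge of the brain had medians in young wild-type and young deficient arrays of 3.17 and 1.35 for pituitary, 1.17 and 0.30 for olfactory epithelium and nerve, and 0.82 and 2.16 for spinal cord and caudal hindbrain. Neuronal and synaptic vesicle genes were higher for 22 of 26 (median 0.13, adjusted p = 0.018; adjusted p = 0.48 with an estimated correlation). Cplx1 was called (0.60 ± 0.12). The list was not called with quantile normalization (0.07, adjusted p = 0.175), in the deposited table, or without array 2 of the young deficient (adjusted p = 0.132) or array 4 of the young wild type (adjusted p = 0.0546). Immediate early genes were lower for 24 of 29 (median -0.35, adjusted p = 0.00068; adjusted p = 0.63 with an estimated correlation). The 1 called member, Jund, was higher (0.48 ± 0.09). On arrays 1 and 4 of the young deficient mice that list stood at -0.67 and -0.58, and without array 1 it was not called (-0.14, adjusted p = 0.101). Of the called members named, Cryab stayed called without each array in turn, whereas the highest adjusted p of the others ran from 0.0534 to 0.123. Oas2 was no longer called with normexp (-0.55, adjusted p = 0.0931), nor Dnaja1 with the mean of its probes (-0.20, adjusted p = 0.182).

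At 18 months 210 genes were higher and 128 lower in the deficient brains, and 277 of the 338 differed by more than 1.5-fold. The homeobox genes Hoxb5 (4.89 ± 0.83, adjusted p = 0.0065), Hoxc4 (4.33 ± 0.90, adjusted p = 0.024) and Hoxa5 (2.93 ± 0.68, adjusted p = 0.046), expressed in hindbrain and spinal cord, were higher in the deficient mice. A set of 11 Hox genes that mark spinal cord and caudal hindbrain, these included, had medians of -0.20 in old deficient and -2.31 in old wild-type arrays, relative to each gene's overall mean. Zfp963 (2.89 ± 0.25, adjusted p = 1.1e-05), Ocel1 (2.44 ± 0.28, adjusted p = 0.00023) and Ccr6 (2.72 ± 0.38, adjusted p = 0.0014) were higher as in the young mice. Ttll2, Opn4 and Slc25a41 were not well above background in old wild type and were at least 4.21-fold, 3.69-fold and 6.24-fold higher (adjusted p = 0.00015, 5.5e-05 and 0.025). Fam227b (3.14 ± 0.54) and Tmem181b-ps (3.09 ± 0.46) also rose.

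Among the falls in old deficient mice, the vomeronasal receptor gene Vmn1r104 was below background in the deficient group and at least 8.26-fold lower (adjusted p = 0.0022). The glypican Gpc2 (-4.28 ± 0.88, adjusted p = 0.023), Ppcdc (-2.93 ± 0.50, adjusted p = 0.0065), the neighbouring chemokines Cxcl5 (-2.41 ± 0.39, adjusted p = 0.0041) and Ppbp (-2.37 ± 0.48, adjusted p = 0.02), Ccl28 (-2.08 ± 0.48, adjusted p = 0.043), Tmem25 (-1.94 ± 0.32, adjusted p = 0.0045), Ccdc153 (-1.73 ± 0.31) and Bco2 (-1.71 ± 0.29, adjusted p = 0.0056) were lower. Transcripts of red blood cells were lower as well, namely Alas2, the first enzyme of heme synthesis in these cells (-2.41 ± 0.53, adjusted p = 0.034), and the beta-globins Hbb-bt (-2.09 ± 0.44, adjusted p = 0.027) and Hbb-b2 (-1.99 ± 0.45, adjusted p = 0.041). The blood list was lower for 15 of 15 members (median -1.40, adjusted p = 4e-10; adjusted p = 0.45 with an estimated correlation). Of these, 3 were called over all genes and 6 adjusted over the list alone. Its medians on the 4 old deficient arrays were -2.17, -1.84, -0.15 and -1.37. In the dimmer group, Hoxb5, Hoxc4, Hoxa5, Gpc2, Ppcdc and Ppbp were well above background on 1 of 4 arrays, Tmem181b-ps on 2 and Ccl28 on 3. Of the 23 genes named by rule and reported, 10 were called under every alternative that tested them and without each array, namely Fam227b, Ttll2, Tmem181b-ps, Zfp963, Ccr6, Opn4, Ocel1, Vmn1r104, Cxcl5 and Ccdc153. Slc25a41, Hoxa5, Ppcdc and Ppbp were no longer called with normexp, with differences more than 1.5 times smaller (adjusted p up to 0.54, for Hoxa5), nor was Hoxa5 in the deposited table (1.12, adjusted p = 0.225).

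Markers of microglia, the resident macrophages of the brain, were lower in old deficient than in old wild-type brains for 21 of 23 members (median -0.27, adjusted p = 4e-10). This was the 1 list of the 6 passing camera that also passed with an estimated correlation (adjusted p = 0.017), and fry gave 0.000296. Its mean level, relative to each gene's overall mean, was 0.23 in old wild type. It was -0.08 in young wild type, -0.11 in young deficient and -0.06 in old deficient mice, so only the old wild type stood apart. The age difference of this list in wild type and its interaction draw on the same old wild-type arrays and are not separate results. Called members were Ly86 (-1.24 ± 0.14, adjusted p = 0.00023) and the lipid receptor Trem2 (-0.78 ± 0.11, adjusted p = 0.0022), and 5 passed when adjusted over the list alone. Oligodendrocyte and myelin genes passed with members going both ways (median -0.16, adjusted p = 0.0086; adjusted p = 0.62 with an estimated correlation). The myelin gene Mobp was higher (0.97 ± 0.13), while Opalin (-0.54 ± 0.12) and the cytokine Il33 (-0.56 ± 0.13) were lower. Cholesterol synthesis genes were lower for 20 of 26 (median -0.11, adjusted p = 0.0086; adjusted p = 0.40 with an estimated correlation). Sc5d was called (-0.64 ± 0.10). Reactive astrocyte genes were higher for 16 of 25 (median 0.07, adjusted p = 0.046; adjusted p = 0.62 with an estimated correlation), a call that ended without any 1 of 7 arrays (adjusted p up to 0.152). Timp1 (1.11 ± 0.20) and Aspg (0.57 ± 0.12) were called. Opalin, Il33 and Aspg lost their calls without any 1 of 7, 12 and 6 arrays, and Mobp with the mean of its probes (0.41, adjusted p = 0.0737).

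Averaged over both ages, 381 genes were higher and 353 lower in the deficient mice, the largest count of the 7 contrasts. Zfp963 (3.01 ± 0.18, adjusted p = 8.2e-08), Ocel1 (2.60 ± 0.20, adjusted p = 1.6e-06), Ccr6 (2.62 ± 0.27, adjusted p = 4.2e-05), Klk1b22 (4.25 ± 0.66, adjusted p = 0.002) and Fam227b (2.65 ± 0.38, adjusted p = 0.001) were among the rises. Shank2, a postsynaptic scaffold gene, was well above background on 8 of 8 wild-type and 3 of 8 deficient arrays and was lower in the latter by this probe (-4.77 ± 1.04, adjusted p = 0.021), while another of its probes, above background on all 16 arrays, gave -0.02 (adjusted p = 0.966). Tmem25 (-2.16 ± 0.22, adjusted p = 4.7e-05), Bco2 (-1.92 ± 0.20, adjusted p = 5.7e-05), Rpp25 (-1.59 ± 0.16, adjusted p = 4.2e-05) and Ccl28 (-2.30 ± 0.34, adjusted p = 0.0012) were lower. So were the small heat shock protein Cryab (-1.16 ± 0.12, adjusted p = 4.9e-05), the proteasome subunit Psmd14 (-0.44 ± 0.08) and the tight junction gene Ocln (-0.49 ± 0.09). Microglial markers were lower for 20 of 23 members (median -0.11, adjusted p = 2.8e-05; adjusted p = 0.20 with an estimated correlation), and 4 were called, namely Ly86 (-0.95 ± 0.10), Trem2 (-0.46 ± 0.08), Fcrls (-0.61 ± 0.16) and the transcription factor Sall1 (-0.30 ± 0.07). Oligodendrocyte precursor genes were lower for 12 of 16 (median -0.08, adjusted p = 0.023; adjusted p = 0.45 with an estimated correlation), where Gpr17 (-0.49 ± 0.09) and Neu4 (-0.49 ± 0.11) were lower and Enpp6, a marker of newly forming oligodendrocytes, was higher (0.83 ± 0.17). The precursor list was not called without array 4 of the old deficient (adjusted p = 0.0532), array 1 of the young deficient (0.146) or array 1 of the old wild type (0.0789). Fcrls and Sall1 lost their calls without any 1 of 12 and 6 arrays, and Enpp6 with the mean of its probes (0.44, adjusted p = 0.102). Monocarboxylate and glucose transporters, a list drawn from several families, did not pass (19 members, median 0.02, adjusted p = 0.739). Slc16a13 was higher (0.32 ± 0.07, adjusted p = 0.015) and the fructose transporter Slc2a5 lower (-0.30 ± 0.08, adjusted p = 0.048). Slc16a13 no longer passed with the mean of its probes (0.16, adjusted p = 0.197), nor Slc2a5 with normexp (-0.27, adjusted p = 0.0743) and without any 1 of 14 arrays (adjusted p up to 0.11). Of the 23 named by rule and reported, 18 stayed called under every alternative that tested them and without each array, and the exceptions were Hoxc4, Hoxb4, Shank2, Nrg4 and Dctd.

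**Figure D2:**
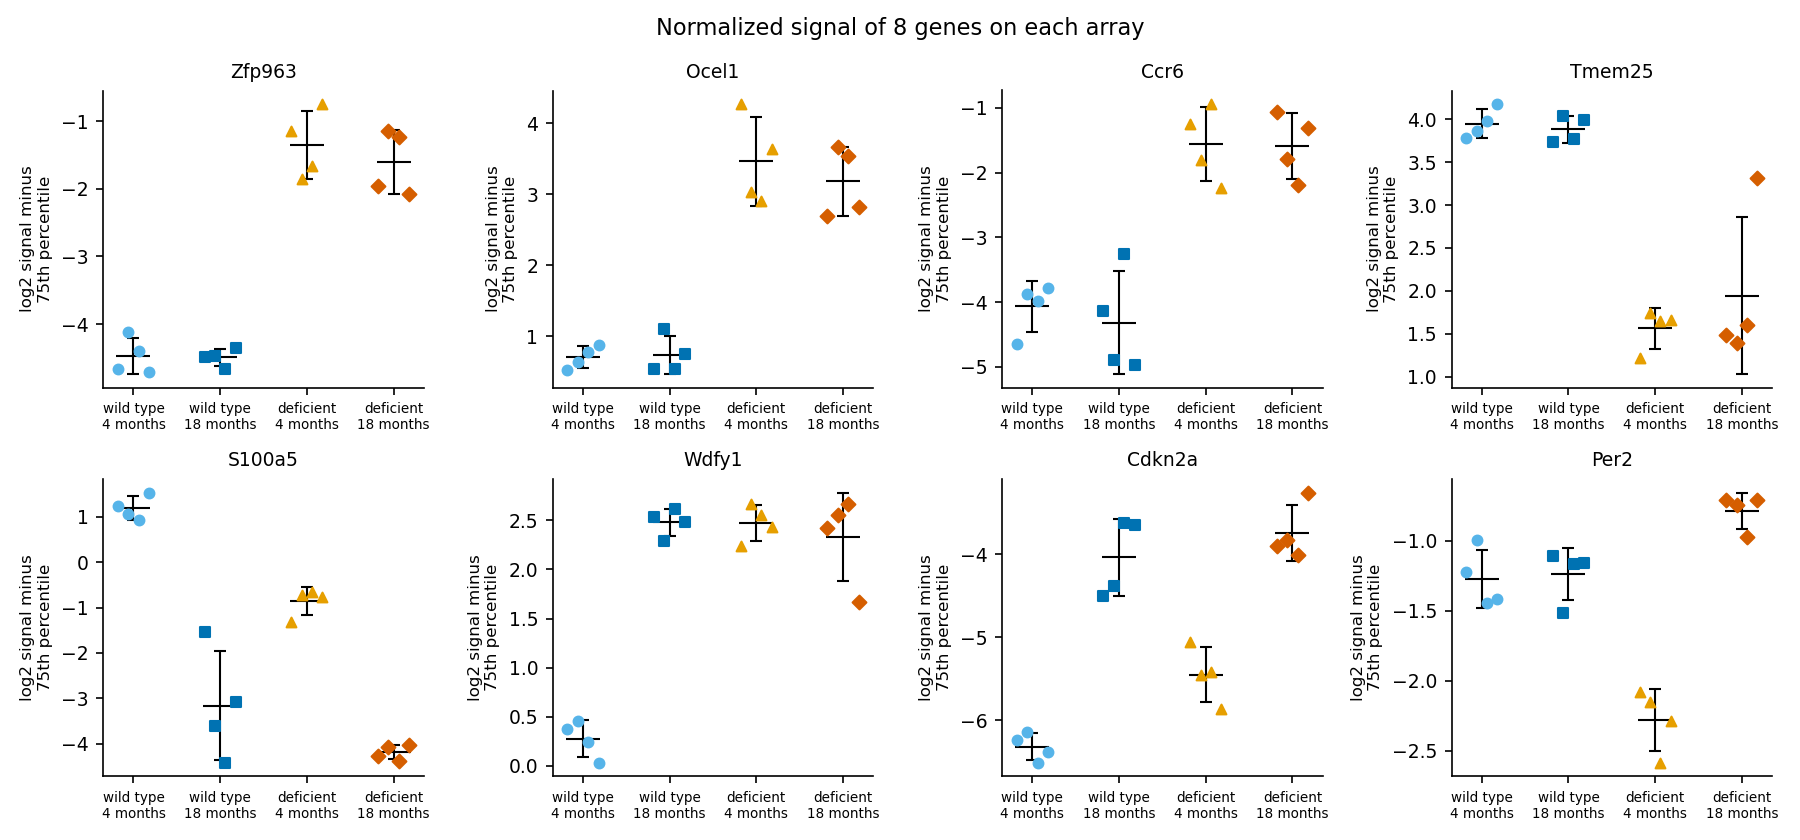
Normalized log2 signal (relative to the array's 75th percentile) of 8 genes, 1 point per array, with the group mean and SD as black bars, for n = 4 arrays per group. Wdfy1 had its lowest mean, 0.28, in the young wild type, and Tmem25 on array 4 of the old deficient mice lay at 3.31 against 1.49 for the mean of the other 3.

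Genes called between the genotypes lay close together on the chromosomes. Among the 292 tested genes within 10 Mb of Slc5a8 on chromosome 10, 20 were called (6.85%), against 714 of 22738 elsewhere (3.14%), an odds ratio of 2.27 (95% interval 1.36 to 3.60, Fisher's exact test p = 0.00125). Netrin Ntn4 belonged to these. Windows of 5 and 20 Mb gave odds ratios of 3.26 and 1.86. For the age difference averaged over both genotypes the odds ratio within 10 Mb was 0.21 (Fisher's exact test p = 0.0973). Over the genome, 11 of 277 windows of 10 Mb held more genotype calls than expected (Fisher's exact test, adjusted p under 0.05), together 175 genes. Gene lists were tested without regard to these windows. List members called between the genotypes, as named above, may therefore lie in them and need not reflect their list. By number of calls the leading windows were chromosome 8 from 70 to 80 Mb with 31 calls among 167 genes (5.32 expected) and chromosome 9 from 40 to 50 Mb with 26 among 118 (3.76 expected). Next came chromosome 4 from 130 to 140 Mb with 23 among 213 (6.78 expected) and chromosome 17 from 0 to 10 Mb with 21 among 89 (2.83 expected). No window was enriched for the averaged age difference by the same test, although 11 had an unadjusted p under 0.05. Its calls were nonetheless closer together than random genes, with 178 pairs between 10 kb and 1 Mb apart against at most 140 in 1000 draws, and 132 against at most 130 for pairs with different name stems. The averaged genotype calls formed 985 such pairs, against at most 478. Within windows the deficient arrays did not sit at 1 level. In the chromosome 8 window, the median difference from the wild-type mean was 0.55 to 0.62 on arrays 1 and 4 of the old and arrays 2 and 3 of the young deficient mice, and 0.89 to 1.11 on the other 4 deficient arrays. Nor did the wild-type arrays sit at 1 level in the chromosome 17 window from 0 to 10 Mb. There the medians were -0.58 to -0.14 on old and 0.17 to 0.45 on young wild-type arrays.

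**Figure D3:**
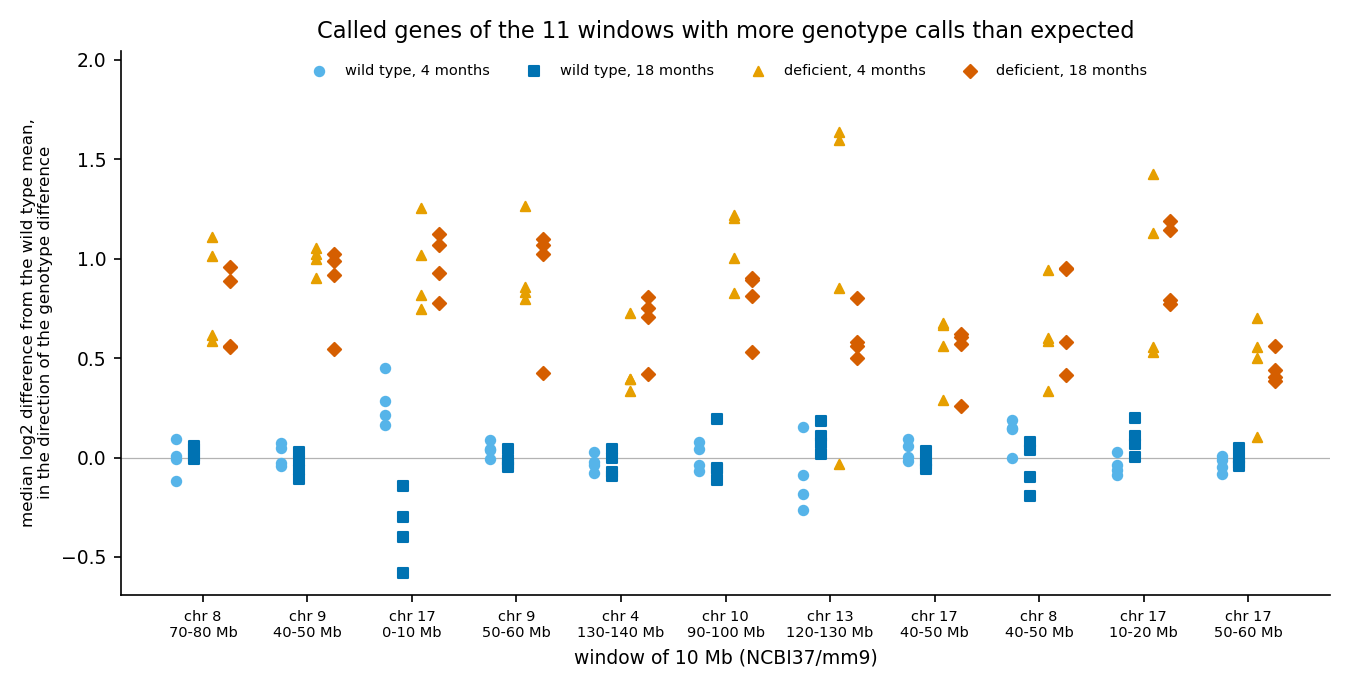
Median log2 difference from the mean of the 8 wild-type arrays, turned to the direction of the genotype difference, over the called genes of each of the 11 enriched windows (NCBI37/mm9), with 1 point per array. The genes were chosen for their genotype difference, so the gap from the wild type is built in, whereas the spread among the deficient arrays is not.

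Between 4 and 18 months 97 genes differed in wild-type mice, 39 higher and 58 lower in the old. Cdkn2a, the locus of cell cycle inhibitors that mark senescent cells, rose by 2.28 ± 0.23 (adjusted p = 1e-04), but by 0.72 with normexp (adjusted p = 0.218, not called). The GABA receptor subunit Gabra2 rose by 1.51 ± 0.17 (adjusted p = 0.00035), Wdfy1 by 2.20 ± 0.18 (adjusted p = 1.2e-05), Cyp2e1 by 1.43 ± 0.26 (adjusted p = 0.019), Fmo2 by 1.09 ± 0.22 (adjusted p = 0.048) and the mitochondrial transhydrogenase Nnt by 1.05 ± 0.21 (adjusted p = 0.039). Wdfy1 stood at 0.28 in young wild type against a mean of 2.43 on the other 12 arrays, young deficient ones included. Its difference is therefore particular to the young wild type and not a rise with age in both genotypes. Cst7 (1.13 ± 0.19, adjusted p = 0.014) and the lectin receptor Clec7a (0.84 ± 0.13, adjusted p = 0.0055), both induced in activated microglia, and Slamf9 (0.86 ± 0.11, adjusted p = 0.0012) also rose. Vmn1r104 rose at least 7.75-fold from below background (adjusted p = 0.0041), Gpc2 by 4.58 ± 0.88 and Fn3krp by 2.38 ± 0.42. Old wild-type arrays lay in row 1 of their slide and young ones in row 2, so age and slide row cannot be told apart in this contrast. Its calls lay close together on the chromosomes, with 67 pairs between 10 kb and 1 Mb apart against at most 25 in 1000 random draws of as many genes, and 41 against at most 21 for pairs with different name stems.

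Among the falls in old wild-type mice, Ms4a15 showed a difference of -5.63 ± 0.60 (adjusted p = 0.00022). S100a5 (-4.35 ± 0.41, adjusted p = 6.5e-05), the olfactory marker protein Omp (-2.97 ± 0.55, adjusted p = 0.025), Tbx21, a transcription factor of mitral and tufted cells (-2.29 ± 0.26, adjusted p = 0.00046), and Doc2g (-1.72 ± 0.25) fell. The list of olfactory bulb and neuroblast genes was lower for 18 of 24 members (median -0.07, adjusted p = 5.6e-05; adjusted p = 0.30 with an estimated correlation), with Tbx21 and Doc2g called and the fry adjusted p at 0.0939. Its median ran from -0.20 without array 3 of the old to -0.03 without array 2 of the young. Hox genes fell too, namely Hoxb5 (-5.34 ± 0.83, adjusted p = 0.0073), Hoxc4 (-4.54 ± 0.90, adjusted p = 0.039), Hoxa5 (-3.36 ± 0.68, adjusted p = 0.047) and Hoxb8 (at least 9.14-fold, adjusted p = 0.032). Marker sets of tissues at the edge of the dissected brain, which hold several of these genes, moved in the same direction. The spinal cord and caudal hindbrain set had medians of 0.82 in the young and -2.31 in the old wild type, an olfactory epithelium and nerve set 1.17 and -0.45, and 5 pituitary genes 3.17 and -3.11. Tmem181b-ps (-2.33 ± 0.46), Plac9a (-2.20 ± 0.31, adjusted p = 0.0033) and Tmem254a (-2.01 ± 0.26, adjusted p = 0.0017) completed the named falls. In the dimmer group, Cdkn2a, Gpc2, Ms4a15, Hoxb5, Hoxc4, Hoxa5 and Tbx21 were well above background on 1 of 4 arrays, Tmem181b-ps on 2 and Cst7 on 3. Of the 23 named by rule and reported, Vmn1r104, Wdfy1, Gabra2, Slamf9, Clec7a, Ms4a15, S100a5, Plac9a and Tmem254a were called under every alternative that tested them and without each array. Besides Cdkn2a, normexp ended the calls of Gpc2, Cst7, Fmo2, Hoxb8, Hoxc4, Hoxa5, Tmem181b-ps and Tbx21, with differences more than 1.5 times smaller, the deposited table those of Gpc2, Cst7, Hoxb8 and Hoxa5, and array weights that of Omp (-1.95, adjusted p = 0.1). Array 3 of the young wild type weighed most, since 58 genes were called without it.

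Microglial markers were higher in old wild-type brains for 21 of 23 members (median 0.29, adjusted p = 3e-13; adjusted p = 0.005 with an estimated correlation). The same old wild-type arrays entered the genotype difference of this list at 18 months. No microglial marker was called over all genes by limma, 10 had an unadjusted p under 0.05, and 9 were called when adjusted over the list alone. Activated microglia genes were higher for 18 of 24 (median 0.15, adjusted p = 1.1e-05; adjusted p = 0.021 with an estimated correlation), with Clec7a and Cst7 called and 7 higher and 2 lower over the list alone. These 2 lists were the only ones of the 17 passing camera that also passed with an estimated correlation. Cell cycle genes were lower for 16 of 22 (median -0.12, adjusted p = 0.00051; adjusted p = 0.054 with an estimated correlation). The cyclin Ccna2 was called (-0.55 ± 0.11), but not with normexp (-0.35, adjusted p = 0.287) or without any 1 of 14 arrays. Cholesterol synthesis genes were higher for 22 of 26 (median 0.15, adjusted p = 6.4e-05; adjusted p = 0.054 with an estimated correlation). Choroid plexus markers were lower for 26 of 26 (median -0.68, adjusted p = 5.9e-12; adjusted p = 0.30 with an estimated correlation), with the fry adjusted p at 0.209. The pituitary and pineal list was lower for 9 of 10 (median -0.96 and mean -2.68, adjusted p = 2.5e-06; adjusted p = 0.22 with an estimated correlation). On array 1 of the young wild type the choroid plexus list stood at 1.58 and the pituitary list at 2.37. Without that array their medians were -0.35 and -0.49 and that of the cell cycle list -0.18, all still called.

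**Figure D4:**
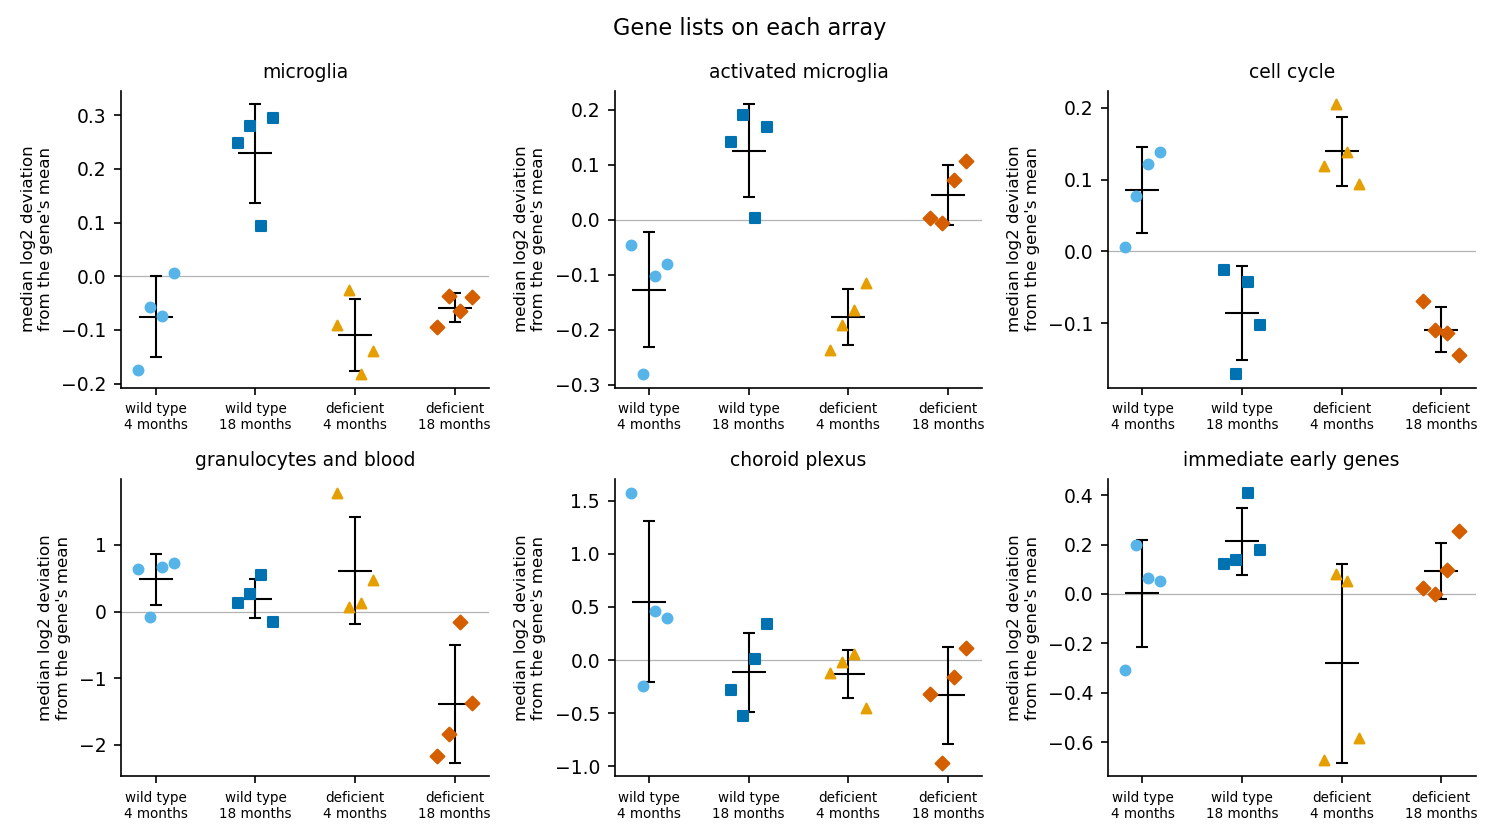
Median log2 deviation of the members of 6 gene lists from each gene's mean over the 16 arrays, 1 point per array, with the group mean and SD as black bars, for n = 4 arrays per group. Microglial markers are highest in the old wild-type arrays, and the blood list on the old deficient arrays lies between -2.17 and -0.15.

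In Slc5a8-deficient mice 291 genes were higher and 259 lower at 18 than at 4 months. Here the old arrays lay in row 2 and the young ones in row 1, so age and slide row again cannot be told apart. Cdkn2a rose by 1.70 ± 0.23 (adjusted p = 0.002; 0.64 and adjusted p = 0.084 with normexp), the clock gene Per2 by 1.49 ± 0.14 (adjusted p = 0.00037) and Sult1c2 by 1.99 ± 0.40 (adjusted p = 0.018). Gimap3 (2.04 ± 0.36, adjusted p = 0.011), the T cell antigen Cd2 (1.42 ± 0.31, adjusted p = 0.027), Ly9 (at least 1.75-fold, adjusted p = 0.024) and Cst7 (at least 2.63-fold from below background, adjusted p = 0.00081) rose as well. The list of lymphocyte and immunoglobulin genes did not pass (11 members, 4 higher, median -0.08, adjusted p = 0.792). Anxa10 was at least 1.42-fold higher (adjusted p = 0.011) and the serine dehydratase Sds was higher by 1.79 ± 0.36 (adjusted p = 0.02). S100a5 (-3.33 ± 0.41, adjusted p = 0.0015), Ms4a15 (at least 9.38-fold, adjusted p = 0.00082), Hoxb8 (-5.21 ± 1.03, adjusted p = 0.017) and Hoxb7 (at least 11.8-fold, adjusted p = 0.022) fell, with spinal cord and caudal hindbrain markers at medians of 2.16 in young and -0.20 in old deficient arrays. Tnnt3, a troponin of skeletal muscle (-2.08 ± 0.38, adjusted p = 0.012), Bglap2, an osteocalcin gene (-2.41 ± 0.41, adjusted p = 0.0089), and Tmem235 (at least 2.05-fold, adjusted p = 0.0097) also fell. Red cell genes fell, with Alas2 at -2.75 ± 0.53, the globin chaperone Ahsp at -2.68 ± 0.52, Hbb-bs at -2.65 ± 0.51, Hbb-bt at -2.27 ± 0.44 and Hbb-b2 at -2.25 ± 0.45. The blood list was lower for 15 of 15 (median -2.02, adjusted p = 8.9e-10; adjusted p = 0.31 with an estimated correlation). Of its members 6 were called over all genes and 12 adjusted over the list alone. Its median was 1.79 on array 1 of the young deficient mice. In the dimmer group, Gimap3, Sult1c2 and Ahsp were well above background on 1 of 4 arrays, Hoxb8 and the later-named Ccnb1 on 2, and Cd2, Tnnt3 and Ccl3 on 3. Of the 24 named genes only Per2, Ms4a15, S100a5 and Bglap2 were called under every alternative that tested them and without each array. Normexp also ended the calls of Gimap3, Sult1c2, Anxa10, Sds, Cst7, Ly9, Cd2, Ahsp, Tmem235 and Tnnt3, with differences more than 1.5 times smaller, and the deposited table those of Sult1c2 and Ly9. Without array 2 of the old deficient mice 149 genes were called.

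None of the 17 lists that passed camera in the deficient mice passed with an estimated correlation (6 at an unadjusted p under 0.05), and fry passed 10. Immediate early genes were higher for 25 of 29 members (median 0.45, adjusted p = 2.6e-06; adjusted p = 0.43 with an estimated correlation), with Inhba (0.92 ± 0.15), the prostaglandin synthase Ptgs2 (0.79 ± 0.15) and Per1 (0.71 ± 0.14) called over all genes and 9 higher over the list alone. The list stood at -0.67, 0.08, 0.05 and -0.58 on arrays 1 to 4 of the young and between -0.00143 and 0.25 on those of the old deficient mice, so arrays 1 and 4 of the young carried most of the difference. Circadian clock genes were higher for 18 of 23 (median 0.28, adjusted p = 0.00089; adjusted p = 0.22 with an estimated correlation). Per2 and Per1 were called, and 7 members when adjusted over the list alone. Cell cycle genes were lower for 18 of 22 (median -0.25, adjusted p = 0.0013; adjusted p = 0.22 with an estimated correlation). The proliferation marker Mki67 (-1.08 ± 0.18), Ccnb1 (-1.29 ± 0.24), Mcm3 (-0.51 ± 0.10) and Ccna2 (-0.51 ± 0.11) were called. Without array 2 of the young deficient mice that median was -0.16 (adjusted p = 0.00924). Interferon-stimulated genes were higher for 24 of 34 (median 0.15, adjusted p = 0.0013; adjusted p = 0.42 with an estimated correlation), with Oas2 (1.07 ± 0.17), Ifit3 (1.05 ± 0.13), Ifit2 (0.57 ± 0.12) and Irgm1 (0.46 ± 0.10) called. Activated microglia genes were higher for 15 of 24 (median 0.26, adjusted p = 0.0051; adjusted p = 0.22 with an estimated correlation), with Cst7, Clec7a (0.99 ± 0.13) and the chemokine Ccl3 (0.95 ± 0.21) called. Reactive astrocyte genes were higher for 15 of 25 (median 0.15, adjusted p = 0.011; adjusted p = 0.42 with an estimated correlation). Complement C4b (1.14 ± 0.13) and Fbln5 (0.48 ± 0.11) were called. Astrocyte markers were lower for 16 of 20 (median -0.17, adjusted p = 0.02; adjusted p = 0.25 with an estimated correlation), but were not called with quantile normalization (adjusted p = 0.123), in the deposited table (0.131) or without array 2, 3 or 4 of the young deficient mice (up to 0.0614). The water channel Aqp4 was lower (-0.67 ± 0.14) and the connexin Gjb6 higher (0.40 ± 0.08). Oligodendrocyte and myelin genes were lower for 19 of 24 (median -0.16, adjusted p = 0.0035; adjusted p = 0.43 with an estimated correlation). Opalin (-0.73 ± 0.12) and Tspan2 (-0.40 ± 0.10) were among the called members that were lower, and Mobp was higher (0.79 ± 0.13). Cerebellar genes were lower for 23 of 24 (median -0.54, adjusted p = 2.6e-06; adjusted p = 0.43 with an estimated correlation), and 9 were called adjusted over the list alone. Of the called members named, Inhba, Per2, Mki67, Oas2, Ifit3, Cst7, Clec7a, C4b, Opalin and Mobp stayed called without each array in turn, and the others did not. Ccl3, Ccnb1 and Ccna2 were not called with normexp (adjusted p of 0.333, 0.109 and 0.0813), nor Mobp with the mean of its probes (0.31, adjusted p = 0.113).

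Averaged over both genotypes, a contrast in which an additive difference between slide rows cancels, 159 genes were higher and 212 lower in old than in young brains. Cdkn2a rose by 1.99 ± 0.16 (adjusted p = 1.1e-05), the dendritic cell lectin Cd209a by 1.26 ± 0.20 (adjusted p = 0.0049), Fmo2 by 1.22 ± 0.16 (adjusted p = 0.00083), Gabra2 by 1.04 ± 0.12 (adjusted p = 0.00034), the defensin Defb1 by 1.90 ± 0.35 (adjusted p = 0.012) and the chemokine Ccl8 by 1.40 ± 0.32 (adjusted p = 0.043). S100a5 (-3.84 ± 0.29, adjusted p = 8.5e-06), Hoxb6 (-3.92 ± 0.67), Hoxb5 (-3.70 ± 0.59), Hoxa5 (-2.90 ± 0.48) and the pituitary hormone subunit Cga (-4.84 ± 1.09, adjusted p = 0.036) fell. Medians of the pituitary, spinal cord and olfactory marker sets, which hold several of these genes, were lower in old arrays of both genotypes. In young and old deficient mice they were 1.35 and -1.45 for pituitary and 2.16 and -0.20 for spinal cord and caudal hindbrain. For olfactory epithelium and nerve they were 0.30 and -0.96. The amount of such tissue in each sample was not tested apart from age, so these falls need not be changes within the brain. Defb1 was well above background on 1 of 4 young arrays of each genotype, Cga on 1 of 4 old wild-type and 2 of 4 old deficient arrays, and Hoxb6 on 1 of 4 old wild-type arrays. Activated microglia genes (median 0.20, adjusted p = 3.3e-05; adjusted p = 0.040 with an estimated correlation) and cell cycle genes (median -0.19, adjusted p = 1.8e-05; adjusted p = 0.040 with an estimated correlation) were the 2 lists of 21 passing camera that also passed with an estimated correlation. The called members were Cst7, Clec7a (0.91 ± 0.09), Gpnmb (0.72 ± 0.12), Ccl3 (0.67 ± 0.15) and Ccl6 (0.43 ± 0.10) in the first list, and Mki67 (-0.93 ± 0.13), Ccnb1 (-1.14 ± 0.17) and Ccna2 (-0.53 ± 0.08) in the second. Clock genes were higher for 19 of 23 (median 0.21, adjusted p = 1.2e-05; adjusted p = 0.056 with an estimated correlation). Per2 (0.76 ± 0.10) and Per1 (0.48 ± 0.10) were called, the latter not without the filter (adjusted p = 0.0661), with the replicate block (0.0739) or without any 1 of 9 arrays (up to 0.0641). Microglial markers were higher for 19 of 23 (median 0.16, adjusted p = 1.3e-05; adjusted p = 0.056 with an estimated correlation). Pericyte, fibroblast and meningeal genes were lower for 19 of 27 (median -0.10, adjusted p = 0.005; adjusted p = 0.33 with an estimated correlation), with the collagens Col3a1 (-0.93 ± 0.16), Col1a1 (-0.89 ± 0.17) and Col1a2 (-0.58 ± 0.12) and Islr (-0.49 ± 0.09) called. That median was -0.16 without array 1 of the young deficient mice. Complement C4b rose by 0.98 ± 0.09 and the chemokine Ccl2 by 0.81 ± 0.17. Ccl3, Ccl6, Col1a2 and Ccl2 lost their calls without any 1 of 10, 12, 7 and 2 arrays. Defb1, Cst7, Ccl8, Cga, Ccl3, Ccnb1 and Ccl2 lost theirs with normexp, with differences more than 1.5 times smaller (adjusted p up to 0.436, for Ccl3), and Cga also in the deposited table. Of the 23 named by rule and reported, 12 stayed called under every alternative that tested them and without each array, among them Cdkn2a, Cd209a, Fmo2, Gabra2, S100a5, Hoxb5, Hoxb6 and Hoxa5. Without array 3 of the young wild type 192 genes were called.

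The interaction asked whether the age difference itself differed between the genotypes, and 43 genes passed, 28 with a more positive and 15 with a more negative old minus young difference in the deficient than in the wild-type mice. Wdfy1 was lowest in the young wild type, at 0.28, against 2.48, 2.47 and 2.33 in old wild type, young deficient and old deficient mice, an interaction of -2.34 ± 0.26 (adjusted p = 0.00056). Per2 stood at -1.27 in young and -1.24 in old wild type, and at -2.28 in young and -0.78 in old deficient mice, an interaction of 1.46 ± 0.19 (adjusted p = 0.0025). Plac9a (2.64 ± 0.44, adjusted p = 0.023), Duxbl2 (2.57 ± 0.33, adjusted p = 0.0024), Tmem254a (2.13 ± 0.37, adjusted p = 0.032) and Tmem254c (1.93 ± 0.33, adjusted p = 0.025) on chromosome 14, and Tmem181a (1.15 ± 0.14, adjusted p = 0.0023) and Dynlt1c (1.25 ± 0.17, adjusted p = 0.0025) on chromosome 17, were lower in old than in young wild type and lay closer to 0 or above it in the deficient mice. The old minus young differences in wild type and deficient mice were -2.20 and 0.44 for Plac9a, -1.86 and 0.71 for Duxbl2, -2.01 and 0.12 for Tmem254a, -0.93 and 0.22 for Tmem181a and -1.43 and -0.18 for Dynlt1c. Plac9a was also lower in young deficient than in young wild-type mice, as given above. Its genotype difference in young mice, its fall with age in wild type and its interaction share the same young wild-type arrays and are not separate results. More positive in the deficient mice too were Inhba (1.23 ± 0.21, adjusted p = 0.028), the histone gene H1f2 (1.36 ± 0.25, adjusted p = 0.04), Upk3bl (1.54 ± 0.27, adjusted p = 0.032) and Gjb6 (0.73 ± 0.12, adjusted p = 0.016). Gpc2 (-6.70 ± 1.25, adjusted p = 0.045) differed by 4.58 with age in wild type and -2.12 in deficient mice, and the phospholipid transfer protein Pltp (-0.82 ± 0.15, adjusted p = 0.045) by 0.19 and -0.62. Clspn stood at -5.33, -6.40, -6.05 and -5.34 (adjusted p = 0.017), and Vmn1r104 at -7.96, -2.98, -5.64 and -7.97 (adjusted p = 0.0051), in young wild type, old wild type, young deficient and old deficient arrays, with at least 1 group not well above background in both. Of 11 lists passing camera, none passed with an estimated correlation (3 at an unadjusted p under 0.05) and fry passed 1, microglia. Microglial markers had a more negative age difference in the deficient than in the wild-type mice for 18 of 23 members (median -0.35, adjusted p = 0.00089; adjusted p = 0.53 with an estimated correlation, fry adjusted p = 0.0402), and blood genes for 14 of 15 (median -1.51, adjusted p = 3.8e-07; adjusted p = 0.61 with an estimated correlation). Duxbl2, Per2, Dynlt1c, Tmem181a and Wdfy1 were called under every alternative that tested them and without each array. Clspn, Upk3bl, Vmn1r104 and Gpc2 were not called with normexp, with differences more than 1.5 times smaller, nor Upk3bl and Gpc2 in the deposited table. The slide rows went with this contrast, since old deficient and young wild-type arrays lay in row 2 and the other groups in row 1. The interaction calls also lay close together on the chromosomes, with 21 pairs between 10 kb and 1 Mb apart against at most 8 in 1000 random draws. For pairs with different name stems there were 14 against at most 7. The called genes are therefore not all separate results.

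Across the 23030 genes the age differences of the 2 genotypes correlated with Pearson's r = 0.159 and Spearman's rho = 0.122, where genes are not independent replicates, and no arrays were shared. Of the genes called with age in both genotypes, 12 rose and 21 fell in both, against 0.49 and 0.65 expected of independent lists, and 7 went opposite ways. Cdkn2a, Clec7a, Cst7, C4b and Fmo2 were among those that rose in both, and Gpr17, Ccna2, Tbx21, S100a5 and Ms4a15 among those that fell in both. The genotype differences of young and old mice correlated with r = 0.195 and rho = 0.0419, and 56 genes were higher and 37 lower in the deficient mice at both ages (1.41 and 1.10 expected), while 6 went opposite ways.

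**Figure D5:**
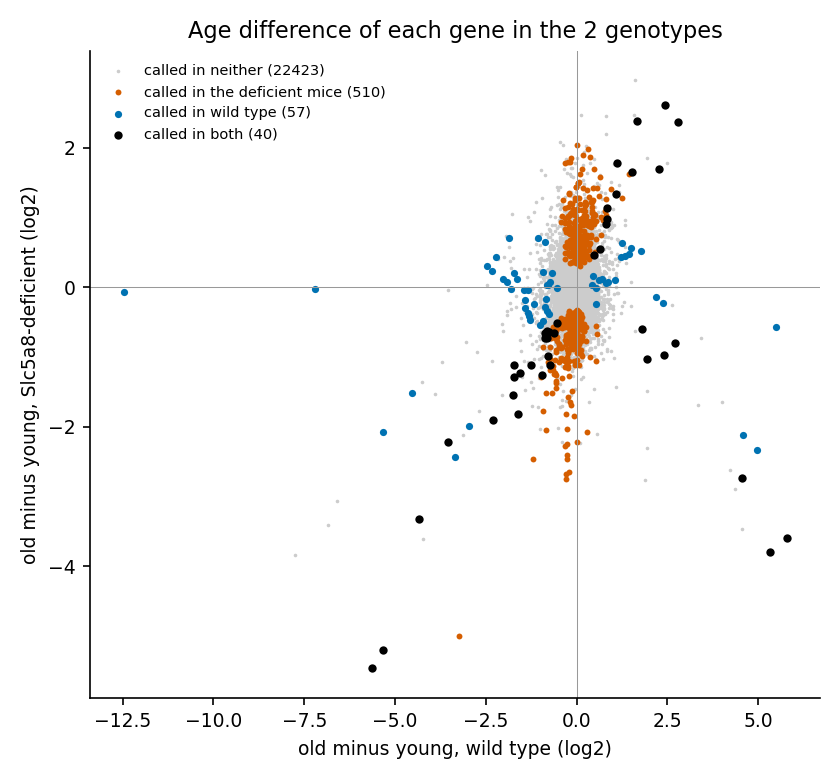
Difference between old and young mice (log2) of each of the 23030 tested genes in wild type (horizontal) and Slc5a8-deficient mice (vertical), with 1 point per gene coloured by the genotype in which it was called. Genes not above background in 1 group are drawn at their fitted difference, and 40 genes were called in both genotypes.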

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

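The tests of slide and scan session, of the 10 Mb around Slc5a8, of DNA differing among the deficient animals, of a DNA difference in the old wild type and of other tissue were chosen after the results were seen.

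Genes called between the genotypes lay close together, with 985 pairs between 10 kb and 1 Mb apart against at most 478 in 1000 random draws of as many genes. Such draws take no account of neighbouring genes varying together. Calls of the averaged age difference, compared within slides, also exceeded their draws (178 pairs, at most 140). The count alone therefore cannot exclude a difference between slides or scan sessions. Neighbouring gene copies that share a name stem did not account for the pattern, since 848 pairs with different name stems were left (at most 437 in the draws). Nor did chromosome 10 alone, since 815 were left without it (at most 411). A named gene and a copy known only by a clone or model number count as different stems, so such copies stay open. Calls were enriched within 10 Mb of Slc5a8 (odds ratio 2.27), as chromosome carried along with the deleted gene there would give. In the 11 enriched windows the deficient arrays of a group spread more than the wild-type arrays in 11 of 11 (median ratio of SDs 3.75, range 1.26 to 6.88). Among other windows this held for 54 of 82 (median 1.34, permutation p = 1e-05, the smallest these permutations can give). The permutations took windows as independent, although all come from the same mice and several adjoin. Windows also differ in how many called genes each median rests on (3 to 31 in the enriched ones), so this p-value cannot decide the question. A candidate explanation, which these values do not settle, is DNA of another strain that still differs among the deficient animals. Array 4 of the old deficient group stood towards the wild type for 4 chromosome 9 genes. Pairs of near genes with an absolute r above 0.95 were 3.67% in the deficient and 0.617% in the wild-type arrays, against 2.83% and 0.501% for genes on different chromosomes. Without array 1 of the young group the deficient arrays gave 0.494% against 0.372%, so this measure does not single out the deficient arrays. Effects of the deletion itself stay open, as does the slide.

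In the old wild type 8 genes were apart from all other 12 arrays by at least 1 log2 unit (4 higher, 4 lower), against 2 such genes in the young wild type and 0 in each deficient group. Probes printed around their spots did not follow (median shift 0.00447, 95% interval -0.041 to 0.032, against 2.66 for the genes), which argues against a local defect of the slide. Of the 7 of these genes with a position, 4 pairs lay between 10 kb and 1 Mb apart against at most 1 in the draws, as near Fam205a2 (1.36 against -1.46 elsewhere) and Gm1987 (3.59 against -2.31) on chromosome 4, both singled out after their values were seen. All these pairs lay at a single place on chromosome 4 and another on chromosome 17. Gene copies were not left out of this count, so copies read by similar probes stay open too. A candidate explanation is a difference in DNA between the old wild-type mice and the other groups, and calls of the wild-type age difference also lay close together (67 pairs, at most 25 in the draws, and 41 against at most 21 with different name stems). An effect of age stays open as untested in these genes, as no genotyping was analysed here.

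Array 1 of the young deficient mice stood apart from the other 15 on the first principal component. RNA loss from the 5' ends is argued against, since its 5' probes were brighter against 3' probes of 1754 transcripts (median shift 0.203, against -0.174 to 0.109 on the other arrays). Blood stays open, since the blood list stood at 1.79 on this array, the highest of the 16 (next 0.72), while another array lay as far above its own group (1.64 against 1.56 here), and the other tissues expected to rise with it did not exceed other arrays, with muscle genes 0.58 above the group (up to 0.67 elsewhere) and pituitary genes -1.70 from it. Low signal stays open too, since over the other 15 arrays the component went with the 75th percentile within groups (r = -0.693, permutation p = 0.0244, and rho = -0.518, permutation p = 0.098), a relation that rests on 2 arrays, with r at -0.447 without those farthest from the median (permutation p = 0.202). No biological explanation was tested.

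In 47 of 664 groups of 4 arrays 1 array stood far from the other 3, where chance gives about 33.2, and each value here is that array minus the mean of the other 3 (log2). Array 1 of the young deficient mice differed in Hbb-bs (1.96), Plac9a (0.82), S100a5 (-0.60), H1f2 (-0.51), Hoxb7 (-2.84), Timp1 (-0.61), Tmem254c (-0.40) and the inhibitory neuron list (-0.24). Array 2 differed in Ccl2 (-0.35) and the list of cell cycle inhibitors (0.18). Array 3 differed in Cga (4.99), Ttll2 (0.90) and the endothelial list (0.0502). Array 4 differed in Aspg (-0.25), Doc2g (-0.90) and Slc25a41 (-3.66). Among the old deficient arrays, array 1 differed in Hoxb7 (2.27) and Mki67 (0.26), array 2 in Pltp (-0.32) and array 3 in Per2 (-0.26). Array 4 differed in Bco2 (1.65), Ppcdc (2.78), Rpp25 (1.04), Tmem25 (1.82) and the protocadherin list (-0.18). Among the old wild type, array 1 differed in Hoxb4 (4.43), and array 2 in Enpp6 (-1.01), Nnt (-0.59), Pcdhb2 (-0.60), Per2 (-0.37), Sult1c2 (-0.91) and the oligodendrocyte list (-0.0801). Array 3 differed in Ccl2 (-0.50), Klk1b22 (2.32) and the cerebellar list (0.53), and array 4 in Cga (3.07) and the inhibitory neuron list (0.18). Among the young wild type, array 1 differed in Gjb6 (0.12), Slc25a41 (-1.05) and the striatal list (-0.51). Array 2 differed in Ccnb1 (0.72), Hbb-bs (-0.49), Sult1c2 (-1.27), the cerebellar list (-0.61) and the blood list (-0.76), array 3 in Mcm3 (0.21) and array 4 in Slc16a13 (0.20).

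The age difference differed between the genotypes by limma's interaction test for 19 named genes. The adjusted p was 5.6e-07 for Gm1987, 6.01e-07 for Fam205a2, 0.000565 for Wdfy1, 0.00229 for Tmem181a, 0.00235 for Duxbl2, 0.00254 for Dynlt1c, 0.00254 for Per2 and 0.00509 for Vmn1r104. It was 0.0158 for Gjb6, 0.0173 for Clspn, 0.0225 for Plac9a, 0.0247 for Mobp, 0.025 for Tmem254c, 0.0278 for Inhba, 0.0317 for Tmem254a, 0.0317 for Upk3bl, 0.0401 for H1f2, 0.0448 for Gpc2 and 0.0448 for Pltp. With the mean of its probes the interaction of Mobp moved from 1.08 to 0.57 (adjusted p = 0.168, not called). Mobp, Inhba and Gjb6 also lost their calls without any 1 of 10, 9 and 2 arrays. For gene lists, camera's adjusted p was 3.79e-07 for blood, 0.000887 for heat shock proteins, 0.000887 for microglia, 0.0117 for interferon-stimulated genes, 0.0119 for reactive astrocytes, 0.0119 for glucocorticoid-responsive genes, 0.0119 for cholesterol synthesis, 0.0133 for choroid plexus, 0.0133 for the unfolded protein response, 0.0414 for striatum and 0.0451 for cerebellum. With an estimated correlation the adjusted p of these lists ran from 0.531 to 0.862. With the preset correlation, choroid plexus lost its call without any 1 of 5 arrays (adjusted p up to 0.695) and cerebellum without any 1 of 6 (up to 0.534). Glucocorticoid-responsive genes lost theirs without either of 2 arrays (up to 0.0681) and cholesterol synthesis without 1 (0.0502). The blood list stayed called without each array.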

How the results depend on the processing

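The alternative without the 3 arrays that stood apart was chosen after seeing the data, and all others were planned. Where a count moved, the cause was not tested unless fewer arrays or genes entered. Counts are given as young genotype, old genotype, wild-type age, deficient age, interaction, mean age and mean genotype (353, 338, 97, 550, 43, 371 and 734 as reported). Array weights gave 2287, 664, 271, 2953, 307, 1769 and 1908, with array 1 of the young deficient mice weighted at 0.103. Without those 3 arrays 261, 458, 101, 639, 57, 466 and 970 genes were called. Normexp gave 52 for wild-type age, 357 for deficient age, 28 for the interaction, 241 for mean age and 15 for calls in both age differences (40 as reported). No filter on dim probes gave 142, 225, 221 for deficient age, 22, 214 and 453. With only the 8 arrays compared, and so fewer degrees of freedom, 74 were called for young genotype and 119 for deficient age. Quantile normalization, the deposited table, the other centring, the stricter filter, other probe choices and the robust trend kept every count within 1.5 times. Of the interaction calls 65.1% were positive, against 45.5% without the filter, 52% with the block and 52.6% without the 3 arrays.

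Replicate numbers did not pair the samples, since arrays of the same number had correlated deviations of -0.44 to 0.27 and 4 of 16 correlated best with their own number. With the replicate number as a block 197, 282 and 25 genes were called for young genotype, deficient age and the interaction, and the other counts stayed within 1.5 times.

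With an estimated correlation 0, 1, 2, 0, 0, 2 and 0 lists passed, and fry passed 5 for young genotype, 6 for wild-type age, 10 for deficient age, 1 for the interaction and 5 for mean genotype. The Slc5a8 difference in young mice turned to -0.14 with quantile normalization and -0.0185 with the deposited table. Cplx2 in young mice turned from 0.23 to -0.37 with normexp and -0.0724 with the mean of its probes. Of the values of named genes under alternatives other than leaving out 1 array, 6033 kept their side of the threshold and 480 no longer passed. A further 221 passed where the reported value did not, and 2 changed sign. With 1 array left out, 7741 kept their side, 899 no longer passed and 96 newly passed. Of the called list members among the genes in the text, 4 of 18, 8 of 18, 3 of 9, 7 of 37, 1 of 4, 16 of 31 and 14 of 24 stayed called under every alternative that tested them and without each array, in the same order of comparisons.

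With 1 array left out, the young genotype count ran from 110 to 407, at 223 and 211 without arrays 2 and 3 of the young deficient and 110, 135, 176 and 199 without arrays 1 to 4 of the young wild type. The old genotype count ran from 181 to 520, at 181 and 211 without arrays 2 and 4 of the old deficient, 212 without array 4 of the old wild type and 520 without array 1 of the young deficient. Wild-type age ran from 58 to 127, at 64 without array 4 of the old and 58 and 64 without arrays 3 and 4 of the young. Deficient age ran from 149 to 659, at 226, 149, 275 and 225 without arrays 1 to 4 of the old deficient, 363 without array 1 of the young deficient and 338 without array 3 of the young wild type. The interaction ran from 21 to 67, at 25 and 26 without arrays 2 and 4 of the old deficient, 67 and 27 without arrays 1 and 2 of the young deficient and 21 and 27 without arrays 1 and 3 of the young wild type, and its lists from 6 (without array 4 of the young deficient) to 13. Mean age ran from 192 to 450, at 211 without array 2 of the old deficient and 192 and 242 without arrays 3 and 4 of the young wild type. Mean genotype ran from 500 to 947. Calls in both age differences ran from 23 to 42, at 26, 26, 25 and 25 without arrays 1 to 4 of the old deficient and 23 and 24 without arrays 3 and 4 of the young wild type. The correlation of the age differences ran from 0.07 to 0.24. The Slc5a8 difference ran from -0.25 (without array 1 of the young deficient, and -0.12 without array 2 of the young wild type) to 0.20 in young mice and from -0.71 (without array 2 of the old deficient, exact permutation p = 0.0286) to -0.31 in old mice, all on a probe not above background.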

Other observations

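The clustered beta protocadherins, adhesion proteins that give neurons their surface identity, were higher in old than in young brains. Averaged over both genotypes 16 of 20 members were higher (median 0.22, camera adjusted p = 3.8e-07; adjusted p = 0.21 with an estimated correlation), and Pcdhb11 (0.83 ± 0.15) and Pcdhb2 (0.86 ± 0.17) were called by limma, though not with normexp (0.23 and 0.26) or in the deposited table (0.29 and 0.41). In the deficient mice alone 17 of 20 were higher (median 0.29, adjusted p = 0.00012; adjusted p = 0.43 with an estimated correlation), with a median of 0.19 without array 1 of the young (adjusted p = 0.00388). In wild type 14 of 20 were higher (median 0.19, adjusted p = 5.2e-05; adjusted p = 0.33 with an estimated correlation), with a median of 0.12 without array 4 of the young (adjusted p = 0.0112). Among cell cycle inhibitors and genes of senescent cells, 11 of 17 were higher with age over both genotypes (median 0.08, adjusted p = 0.022; adjusted p = 0.20 with an estimated correlation), a call that ended with normexp (adjusted p = 0.0531) and without array 4 of the old (0.101) or array 2 of the young wild type (0.0657). Without array 1 of the young deficient mice the median was 0.04. The called members included Cdkn2a, Ccl8 and Ccl2, of which Ccl8 and Ccl2 lost their calls without any 1 of 13 and 2 arrays. In the deficient mice heat shock proteins were higher in old brains for 21 of 25 members (median 0.20, adjusted p = 0.002; adjusted p = 0.43 with an estimated correlation), with the chaperone of the endoplasmic reticulum Hspa5 (0.59 ± 0.14) and Dnajb4 (0.50 ± 0.12) called, but not without any 1 of 11 and 10 arrays. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was higher in old than in young deficient mice (0.60 ± 0.10, adjusted p = 0.0073), but not called with only the 8 arrays compared (adjusted p = 0.0573). Markers of brain regions moved apart with age over both genotypes, with cerebellar genes lower for 24 of 24 members (median -0.42, adjusted p = 2.8e-08; adjusted p = 0.28 with an estimated correlation) and hippocampal genes higher for 18 of 21 (median 0.19, adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation). The hippocampal list stood at 0.61 on array 2 of the old deficient and -0.45 on array 1 of the young wild type. It was not called without the former (median 0.13, adjusted p = 0.0574) or without array 2 of the old wild type (0.18, adjusted p = 0.0534).

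Lists of the transport and use of the transporter's substrates did not pass between the genotypes. Monocarboxylate and glucose transporters had medians of 0.02 in young (adjusted p = 0.881) and 0.01 in old mice (adjusted p = 0.779). Glycolysis and lactate genes had medians of 0.06 (adjusted p = 0.518) and -0.03 (adjusted p = 0.779), and genes of ketone body and fatty acid oxidation 0.08 (adjusted p = 0.296) and 0.03 (adjusted p = 0.588). The 46 nuclear genes of the respiratory chain had a median of 0.10 in young deficient mice (adjusted p = 0.085) and 0.03 in old (adjusted p = 0.588).

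The real grouping of the arrays was compared with other groupings of the same arrays. For each contrast, fewer than 1 in 20 groupings called as many genes. The genotypes lay on different slides and the ages of a genotype in different rows, so the other groupings mixed these too. A slide or row difference could also single out the real grouping. The counts therefore do not tell it from genotype, from age within a genotype or from the interaction. For the young genotype difference the real split called 353 genes and the highest of the other 34 splits 1, so 1 of 35 splits, the real one, reached that count. The old genotype difference gave 338 against 1, age in wild type 97 against 0 and age in deficient mice 550 against 13, again with 1 of 35 splits. Of 100 draws, 1, the real grouping itself, reached the real count of 371 for the averaged age difference (highest other 9), of 734 for the averaged genotype difference (highest other 18) and of 43 for the interaction (highest other 1). For the interaction the draws were of another kind. There the additive genotype and age differences were first removed, and what was left was regrouped at random over the arrays. The correlation of the age differences of both genotypes was reached by 21 of 100 draws, the real grouping included (0.159 against a highest of 0.486), so chance was not excluded for it.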
